A study of Mus musculus with 67 samples.

How the data were processed

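mRNA was measured in 46 hepatocyte and 18 ES cell libraries, and small RNA in 1 hepatocyte and 2 ES cell libraries. Groups follow the labels: virus dose and site in hepatocytes, eYFP bin and construct in ES cells, with 2 libraries per group. Per the submitters' processing notes, STAR 2.4, Cufflinks 2.2.1, Cuffdiff 2.2.1 and the mm10 genome were used, with no role or order stated for each. The authors deposited gene-level FPKM values per library with a confidence interval, and FPKM values per group of 2 libraries in pairwise tables. Those deposited tables also hold a log2 fold change, a p value and a q value for each gene. For small RNA the deposited table holds read counts per miRNA and the RPM scaled from them by the authors. 1 deposited column is a text label of the locus that holds no measured unit. Read or fragment counts of mRNA were not used here, and neither were tools that need counts. Locus starts in the deposited tables count from 0, so 1 was added.

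Per library FPKM was joined by Ensembl gene ID, with gene symbols as given in the files. Of 27298 hepatocyte and 27300 ES gene IDs, entries with a repeated ID (30 in each set) were left out before this count, and genes marked as failed in any library were dropped (8 and 25), which left 27290 and 27275. Values were divided by a median-ratio factor computed without Aldoa, which takes a large share of the reads, over genes above 0 in every library, and log2(FPKM + 1) was taken. Genes with a mean of 1 FPKM or more over the libraries of a fit were tested, 10421 in hepatocytes and 12264 in ES cells for single comparisons. limma 3.58.1 in R 4.3.3 was used with an intensity trend and robust moderation. A fit with 1 mean per group had 23 residual degrees of freedom in hepatocytes and 9 in ES cells. It gave the 22 single comparisons of a site group with its control group, which is shared at a dose or bin. The control had no site for the miRNA tested, and at MOI80 it had a let-7 site. Pooled fits had dose or bin as a term beside the site, the dose fits had the arm as a term, and the bin fit had the construct. p-values were adjusted by Benjamini and Hochberg and 0.05 was the threshold. SE is from the limma fit and SD is over the libraries of a group.

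Genome sequence was not used here, so 3' UTRs were not searched for sites. Predicted targets, the comparison of UTR lengths, the ranking of 7mers and the genes named for their 8mers were therefore not analysed here. Lists of known targets, written from background knowledge before the data were examined, took their place, for let-7, miR-92, miR-122, miR-194, miR-192 and the miR-290 family with the AAGUGCU seed. miR-293 has another seed and has no list. Further lists, fixed at the same time, were hepatocyte function, acute phase, interferon response, NF-kB and cytokine, p53 response, cell cycle, ER stress and amino acid response, glycolysis without Aldoa, cholesterol synthesis, miRNA machinery, pluripotency, primed and early differentiation, 2-cell-like, and markers of Kupffer cells, liver endothelium, stellate cells, cholangiocytes and lymphocytes. They made 24 lists. The comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined, apart from those named as chosen later.

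A list's shift is the mean log2 change of its members minus that of all other genes tested. It was tested with camera, at a preset correlation between genes of 0.01 and again with an estimated one, in lists with at least 3 members, and adjusted over the 19 own-list comparisons or over the lists of a comparison. For pooled comparisons the list score of each library was also tested by permuting libraries within dose or bin, over all arrangements (exact, two-sided). The reporter ratio was tested the same way. Differences between doses and between site types were tested as contrasts of their own. miRNA families were summed by seed, in RPM of all miRNA reads, with exact 95% binomial intervals that cover counting error only.

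Named genes were, for each pooled comparison, the miR-192 comparison, the MOI80 comparison, virus dose and eYFP bin: Aldoa; up to 10 genes with the largest change among those past the threshold and separated in every stratum; up to 8 called members of the miRNA's own list by p, or the 4 with the highest expression if none was called; and 2 to 4 members of every other list mentioned. Part of the written rule, up to 8 called genes with an 8mer in the 3' UTR, was not run. Genes of the single comparisons fall outside the rule.

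The fits were tested on simulated libraries with the gene means and spreads of the data, in which 200 genes were changed by a known amount. In the MOI63 8mer design, 9% of genes changed by 0.25 log2 were recovered, 76.1% at 0.50 and 95.5% at 1. In the pooled 8mer design the shares were 44.8%, 94% and 100%. In a single ES bin they were 0%, 9% and 59.1%, and in pooled ES bins 11.9%, 65.7% and 87.9%. Unchanged genes called numbered 10 in the MOI63 8mer design, 7 in the pooled 8mer design, 2 in a single ES bin and 6 in pooled ES bins. Of 20 simulated lists of 30 genes raised by 0.1 in the pooled 8mer design, the permutation test found 20, and it called 1 of 20 unchanged lists. The simulated noise was independent between genes and each change was the same at every dose or bin. The data need not follow either, so these shares may be too high for them.

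Sequencing lanes were read from the names of the deposited library files where these give one. Libraries that stand apart were those whose distance to the rest of their dose or bin exceeded 1.5 times the median, a rule made after the data were seen. The alternatives tried were a pseudocount of 0.1, no filter and a filter at 10 FPKM, no scaling, quantile normalization, the replicate number as a block, only the 2 groups compared, an expression-matched background with 20 genes per member, an estimated correlation, miRNA shares without the most abundant miRNA, and leaving out each library. The replicate number was also tested for pairing across groups. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and figures. The authors' own comparisons, as deposited from Cuffdiff, call 79 genes at MOI63 with the 8mer (2 higher, 77 lower) and 32 with the 6mer (all lower). At MOI11 they call 213 with the 7mer and 18 with the 8mer, all lower. They also call 13 at MOI80 (7 higher, 6 lower) and 12 with miR-194 at MOI120 (3 higher, 9 lower). The limma calls at MOI63 were instead 133 higher and 122 lower with the 8mer, and 97 and 101 with the 6mer. The cause of this disagreement was not tested. In ES cells the authors' comparisons call 21 with miR-92 in the high bin, and 19 with miR-293 and 16 with miR-92 in the intermediate bin.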

Results

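The series measured mRNA in 64 libraries and small RNA in 3. Primary hepatocytes of C57BL/6 mice were infected with an adenovirus that expresses the Aldoa transcript with or without a site for a miRNA, at doses given as multiplicity of infection (MOI). They gave 46 mRNA libraries in 23 groups of 2. The controls at MOI20 and in the first MOI63 set are labelled as lacking a miR-122 site. At MOI80 the control is labelled with a let-7 site, and the remaining controls as having no sites. All but the MOI80 control are called no-site here. Feeder-free E14 embryonic stem (ES) cells carried a Tet-inducible reporter that makes eYFP and mCherry, where the mCherry transcript had either no site or 3 sites matching miR-293 or else miR-92, and were sorted into 3 bins by eYFP fluorescence. They gave 18 mRNA libraries in 9 groups of 2. Read totals were not used here, and depth was read from the width of the FPKM intervals. It came to an implied 3.94 to 11.04 M fragments in hepatocytes and 4.47 to 29.8 M in ES cells. These are not counts and may not follow true depth, since the interval of Aldoa did not follow its level. Between 9947 and 10598 genes reached 1 FPKM in hepatocytes and between 11800 and 12744 in ES cells. The numbers 1 and 2 in a group were treated as replicates, and since the sources used here do not say whether they are separate animals or cultures, p-values measure only the spread between samples, which may be technical.

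The first question was how much of each miRNA the cells hold. miR-122, the main miRNA of the liver, stood at 302991 RPM, scaled to all miRNA reads, in the 1 hepatocyte library (exact 95% interval 302718 to 303265), or 30.3% of 10840186 reads. miR-21a followed with 200424 RPM. The 9 miRNAs with the let-7 seed held 74801 RPM together, miR-194 held 29676 and the miR-192 family held 19227. In the 2 ES libraries, with 6567029 and 8720659 miRNA reads, miR-294 led with 155568 and 148321 RPM. miR-293 held 63228 and 68366, and the 6 miRNAs of the miR-92 family held 30276 and 27443. miR-293 stood at 41 RPM in hepatocytes and let-7 at 1003 and 995 in ES cells. The intervals cover counting error only, and 1 hepatocyte library gives no measure of replicate spread.

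The second question was whether Aldoa with miR-122 sites changes the level of other miR-122 targets. At MOI63 with a full 8mer site, 9 of the 33 measured genes on a list of known miR-122 targets rose, and 0 fell. Slc7a1, a cationic amino acid transporter (ENSMUSG00000041313, chromosome 5, 148327410 to 148399904, mm10), rose by 0.73 log2 ± 0.069 (SE), from 8.64 ± 0.0795 to 16.0 ± 0.156 FPKM (SD, n = 2 per group; limma adjusted p = 1.15e-07). Cs, the citrate synthase of the Krebs cycle, rose by 0.38 ± 0.054, from 70.5 ± 1.73 to 98.2 ± 2.84 FPKM (limma adjusted p = 2.2e-04). Clic4, a chloride intracellular channel protein, rose by 0.42, and Hfe2, the hemojuvelin gene of iron regulation, by 0.50. Rell1, Iqgap1, Slc35a4 and Cers6 rose by 0.33 to 0.52. Adjusted over the list alone, 15 members rose. The list as a whole rose by 0.24 against all other genes, with 26 of 33 members above 0 (camera, adjusted p = 1.53e-09 over 19 comparisons, and adjusted p = 1.69e-06 with an estimated correlation). Some members also stood higher without a miR-122 site. Hfe2 stood at 0.348 with a let-7 site at MOI63, and Slc35a4 and Cs at 0.293 and 0.118 with a miR-192 site at MOI120, none of them called.

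Of all 10421 genes tested at MOI63 with the 8mer, list members included, 133 were higher and 122 lower, and 124 of those higher were outside the list. Mib2, a ubiquitin ligase, fell by 0.94, and Ndufb7, a subunit of respiratory complex I, fell by 1.04. Of the other lists, cholesterol synthesis rose by 0.13, with Fdps called at 0.36 (adjusted p = 0.0115, and adjusted p = 0.260 with an estimated correlation). Replicate 2 of the 8mer group stood 1.81 times as far from the rest of its MOI as the median library did. Without it 30 genes were called, and without replicate 1 1028 were called. Without no-site replicate 1 and without no-site replicate 2, 43 and 99 were called. Without scaling the split was 736 higher and 78 lower, and 0 genes passed when limma saw only these 4 libraries. The named genes kept their direction in both, but the same libraries are compared there, so this adds no support. Slc7a1, Cs and Clic4 were called whichever of the 4 libraries was left out. The genes of the single MOI63 comparisons named in this text were chosen after their values were seen.

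A separate set at MOI80 compared Aldoa with both an 8mer miR-122 and an 8mer let-7 site to Aldoa with the let-7 site only. All 33 members of the miR-122 list lay above 0, 7 rose (11 adjusted over the list alone), and the list rose by 0.26 (adjusted p = 1.46e-24, and adjusted p = 3.53e-10 with an estimated correlation). Slc7a1 rose by 0.73 ± 0.069, from 10.6 ± 0.278 to 19.6 ± 0.287 FPKM (SD, n = 2; limma adjusted p = 2.63e-07). Hfe2 rose by 0.61, Slc35a4, a nucleotide sugar transporter family member, by 0.68, and Agpat1, an acyltransferase of phospholipid synthesis, by 0.80. Cs, Rell1 and Clic4 rose by 0.39, 0.54 and 0.34. In all 37 genes were higher and 11 lower of 10421. The lipid droplet gene Cidec rose by 1.46, the channel gene Panx1 rose by 0.98, and Gemin4, of the SMN complex, fell by 0.84. The let-7 list was higher by 0.11 with 1 member (Cpeb1) past adjustment over the list alone (adjusted p = 0.00642, and adjusted p = 0.0396 with an estimated correlation), although both arms carry a let-7 site. The stress list of endoplasmic reticulum (ER) and amino acid genes was higher by 0.12, with Asns called at 0.35 (adjusted p = 0.00496, and adjusted p = 0.223 with an estimated correlation). The 77 ribosomal protein genes were lower by 0.15 on average (p = 0.0385 with an estimated correlation), and by 0.039 without scaling and 0.079 after quantile normalization. Leaving out a library left 21 (replicate 2 of the arm with both sites) to 64 genes called, and 30 without replicate 1 of the arm with the let-7 site. In a limma fit of these 4 libraries alone, 0 passed. Without scaling 148 genes were higher and 8 lower, and without the filter 47 and 30.

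At lower virus doses the shift of the same list was smaller. With the 8mer it rose by 0.048 at MOI11 (adjusted p = 0.0481, and adjusted p = 0.0326 with an estimated correlation) and by 0.091 at MOI20 (adjusted p = 6.8e-05, and adjusted p = 2.1e-04 with an estimated correlation). The MOI11 value lost its call without replicate 2 of the no-site group (0.029) and without replicate 2 of the 8mer group (0.039). It also lost it with the replicate number as a block (adjusted p = 0.0572), after quantile normalization (adjusted p = 0.0644) and against a background matched on expression (adjusted p = 0.0928). The shift at MOI63 exceeded that at MOI11 by 0.19 (adjusted p = 5.5e-10), a test of the difference itself, and MOI20 was not tested against MOI63. Pooled over the 3 doses, the list score was 0.13 higher with the 8mer, and both site libraries lay above both no-site libraries at every dose (exact permutation test over every arrangement within dose, two-sided p = 0.00926, the smallest it can give; adjusted p = 0.0185 over 6 tests). In the pooled fit camera gave adjusted p = 2.64e-08 over the lists, a call lost with an estimated correlation (adjusted p = 0.302). No gene passed in the pooled fit of 10466 genes (limma; 1002 at unadjusted p under 0.05), while 13 list members passed when adjusted over the list alone, all higher. Among them Slc35a4 stood at 0.36, Slc7a1 at 0.34 and Cers6, a ceramide synthase, at 0.26. Pooled fits assume the same site effect at every dose, so an effect that grows with dose widens their residual spread. Genes with such an effect are harder to call there. At MOI11 the 1 gene called was Aldoa itself, and at MOI20 none was (limma; 371 at unadjusted p under 0.05). The 8mer and no-site libraries shared a sequencing lane at MOI11 and at MOI20, so those values are within a lane. At MOI63 the value within lane 3, without 8mer replicate 2, was 0.24.

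**Figure D1:**
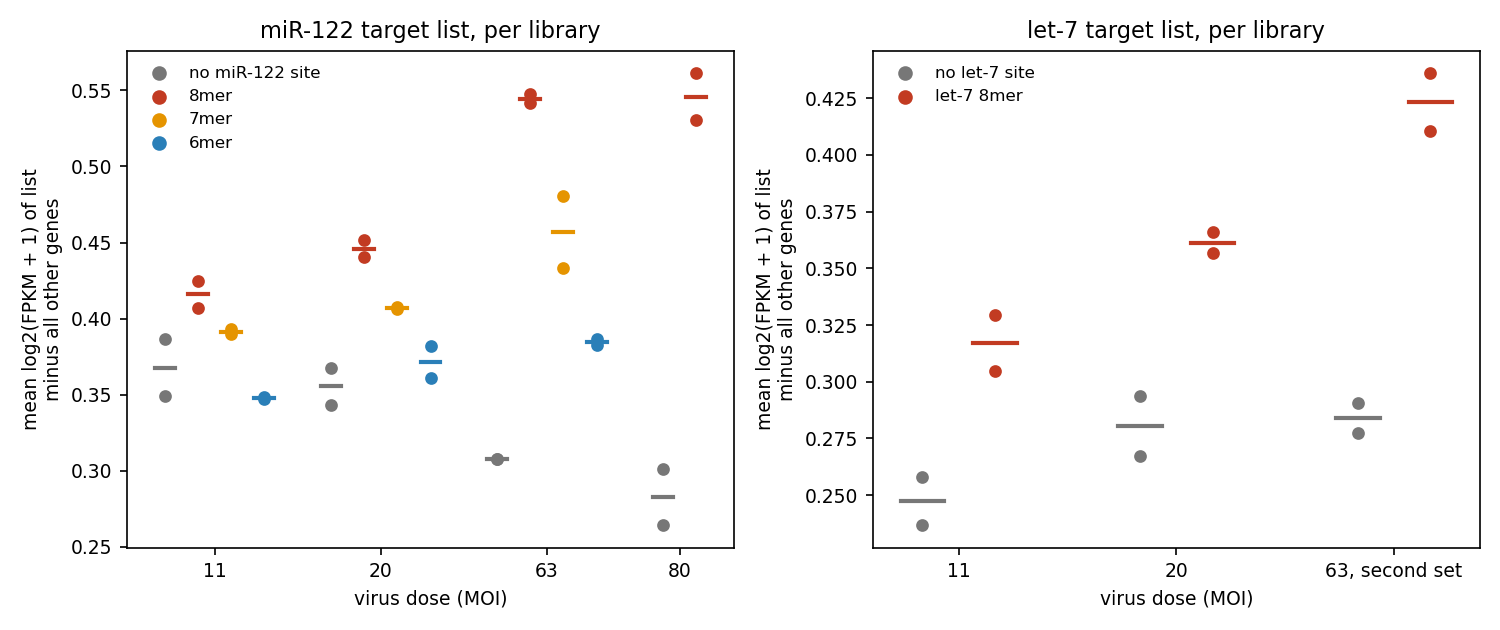
Mean log2(FPKM + 1) of the target list minus that of all other genes (y axes, log2 units; they do not start at 0) against virus dose in MOI (x axes), 1 point per library and a bar for the mean of n = 2. At MOI63 the miR-122 score was 0.308 with no site and 0.545 with the 8mer, and at MOI80 it was 0.283 and 0.546.

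The third question was how the match of the site matters. At MOI63 the miR-122 list rose by 0.15 with a 7mer (adjusted p = 6.3e-07, and adjusted p = 2.21e-05 with an estimated correlation) and by 0.077 with a 6mer (adjusted p = 0.0248, and adjusted p = 0.0222 with an estimated correlation). Slc7a1 and Cs rose by 0.36 and 0.33 with the 7mer, and by 0.34 and 0.29 with the 6mer. Iqgap1, a scaffold of the cytoskeleton, and Clic4 also rose with the 6mer, by 0.29 and 0.24. Adjusted over the list alone, 9 members rose with the 7mer, and with the 6mer 4 rose and 1 fell. The 6mer list call was lost without no-site replicate 1 (0.077, adjusted p = 0.0543) and without 6mer replicate 2 (0.079, adjusted p = 0.0876). At MOI20 the 7mer list shift was 0.052 (adjusted p = 0.0248), a call lost without no-site replicate 2 (0.039) and without 7mer replicate 1 (0.052) or 2 (0.051). At MOI11 it was 0.024 (adjusted p = 0.352), but with a filter at 10 FPKM it was larger and passed the threshold. The 6mer shifts at MOI20 and MOI11 were 0.016 (adjusted p = 0.352) and -0.020 (adjusted p = 0.414). Set directly against each other and pooled over doses, the 8mer exceeded the 7mer by 0.052 and the 6mer by 0.10 (exact permutation, p = 0.00926 each, the smallest possible). At MOI63 the 8mer exceeded the 7mer by 0.088 (adjusted p = 0.01004) and the 6mer by 0.16 (adjusted p = 4.51e-06). Against the no-site libraries, the pooled list score was higher by 0.075 for the 7mer (exact permutation p = 0.00926; camera adjusted p = 5.45e-04, and adjusted p = 0.289 with an estimated correlation) and by 0.025 for the 6mer (exact permutation p = 0.204). All arms at a dose share their no-site libraries, so their shifts are not independent. The 7mer and 6mer libraries ran in other lanes than the no-site libraries at every dose, and than the 8mer libraries at MOI11 and MOI20, so lane and site cannot be told apart there. Within lane 4 at MOI63, without 8mer replicate 1, the 8mer exceeded the 7mer by 0.085 (adjusted p = 0.0621) and the 6mer by 0.16.

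Gene by gene, 12 genes were higher and 7 lower with the 7mer at MOI63, and 97 were higher and 101 lower with the 6mer. Ribosomal protein and nuclear respiratory chain genes were among those lower with the 6mer. Of 77 ribosomal protein genes 11 fell, with a mean of -0.30 (p = 0.0155 with an estimated correlation), and of 80 respiratory chain genes 12 fell, with a mean of -0.25 (p = 0.00391 with an estimated correlation). Against the same no-site libraries these classes stood at -0.16 and -0.11 with the 8mer and at -0.12 and -0.12 with the 7mer (p = 0.365, 0.396, 0.162 and 0.0441 with an estimated correlation). The 13 genes encoded in mitochondria stood at 0.20 with the 6mer (p = 0.141 with an estimated correlation). These classes were read only after the counts were seen. Without 6mer replicate 1 the ribosomal and respiratory means were -0.21 and -0.16, and without no-site replicate 2 they were -0.23 and -0.19, with 0 genes of either class called in both cases (p = 0.0407, 0.0160, 0.0683 and 0.0240 with an estimated correlation). The calls of single genes in these classes thus rest on 6mer replicate 1 and no-site replicate 2, while both class means stayed below 0. Without no-site replicate 1 the ribosomal and respiratory means were -0.37 and -0.31, and without 6mer replicate 2 they were -0.40 and -0.33. Both 6mer means were below 0 without scaling (-0.31 and -0.26) and after quantile normalization (-0.15 and -0.20). Without scaling the 7mer split was 10 higher and 1 lower, and after quantile normalization it was 35 and 11 for the 7mer and 153 and 84 for the 6mer. Replicate 1 of the 6mer group stood apart by 1.52 times the median. Without it 5 genes were called, without replicate 2 487, and without replicate 2 of the no-site group 6. The 7mer count was 5 without no-site replicate 2, 6 without 7mer replicate 1 and 12 without 7mer replicate 2. Pooled over doses 0 genes passed for the 7mer (limma; 1222 at unadjusted p under 0.05) and 0 for the 6mer (limma; 718). At MOI11 the pseudogene Rpsa-ps10 fell by 1.07 with the 7mer, the 1 gene called (1930 at unadjusted p under 0.05, and 984 called when limma saw only these 4 libraries), and with the 6mer 0 were (limma; 112 at unadjusted p under 0.05). At MOI20 both counts were 0 (limma; 270 and 231 at unadjusted p under 0.05). Interferon response genes stood at -0.099 and -0.077 in the pooled 6mer and 7mer tests (adjusted p = 0.00619 and 0.0400, and adjusted p = 0.694 and 0.779 with an estimated correlation). The miR-192 and miR-290 family lists were higher in the 7mer test by 0.057 and 0.064, and acute phase genes stood at -0.076 (adjusted p = 0.362, 0.496 and 0.362 with an estimated correlation). Cholesterol synthesis genes were higher by 0.065 and 0.058 (adjusted p = 9e-04 and 0.0091, and adjusted p = 0.601 and 0.362 with an estimated correlation).

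A let-7 site was tested in the same way. The let-7 list rose by 0.070 at MOI11 (adjusted p = 0.0196), by 0.081 at MOI20 (adjusted p = 0.0115) and by 0.14 in the second MOI63 set, where 22 of 25 members lay above 0 (adjusted p = 5.6e-08, and adjusted p = 5.67e-05 with an estimated correlation). Over the 3 doses the score was 0.097 higher, with each site library above each no-site library of its dose (exact permutation p = 0.00926; adjusted p = 0.0185). No gene passed in the pooled fit (limma; 372 at unadjusted p under 0.05). Adjusted over the list alone 5 members passed, all higher, and they were named after their values were seen. They are the growth factor receptor gene Tgfbr1 (0.17), the chromatin genes Hmga2 (0.34) and Arid3b (0.35), the RNA-binding Igf2bp2 (0.24) and the miRNA-processing Dicer1 (0.16). Without a let-7 site, Tgfbr1 stood at 0.195, 0.153 and 0.129 in the pooled 7mer, 8mer and 6mer fits. It stood at 0.17 in the pooled miR-194 fit, and Hmga2 stood at 0.182 in the pooled 7mer fit. None of these was called, but the rise of Tgfbr1 is not particular to the let-7 site. The members with the highest expression, Hmga1, Eif4g2, Cdc34 and Rdx, stood at 0.10, 0.02, 0.12 and 0.02 with adjusted p = 0.999. At MOI63 Fignl2 rose by 0.65, the 1 gene called, and it is on no list. Its call was lost with a pseudocount of 0.1, with the replicate number as a block and with only the 2 groups compared. None was called at MOI11 or MOI20 (limma; 428 and 488 at unadjusted p under 0.05). The shift at MOI63 exceeded that at MOI11 by 0.069 (adjusted p = 0.0822), which does not pass. Interferon response genes were lower in the pooled let-7 test, at -0.14, and in the second MOI63 set, at -0.26 (adjusted p = 5.02e-08 in the first, and adjusted p = 0.433 and 0.765 with an estimated correlation). Genes of the miRNA machinery, Dicer1 among them, stood at 0.057 (adjusted p = 9.6e-04, and adjusted p = 0.248 with an estimated correlation). The let-7 and no-site libraries shared a lane at MOI11 but not at MOI20, where lane and site cannot be told apart. The list's calls at MOI11 and MOI20 were lost without let-7 replicate 1 (0.058) and let-7 replicate 2 (0.076). Both calls were also lost with a filter at 10 FPKM.

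For miR-194 and miR-192 the lists did not pass as a whole. The miR-194 list stood at 0.041 at MOI60 (adjusted p = 0.304) and at 0.082 at MOI120 (adjusted p = 0.118). Pooled, its score was 0.070 higher (exact permutation p = 0.167, where 36 arrangements allow no p under 0.0556). Hbegf, a growth factor and known miR-194 target, was called at MOI120 and rose by 0.61. There 46 genes were higher and 18 lower, among them the nuclear long RNA Malat1, which fell by 1.32. Both were chosen after their values were seen. Without scaling the split was 76 and 6, and after quantile normalization 33 and 7. Replicate 2 of the miR-194 group stood apart by 1.78 times the median, and without it 4 genes were called. Without no-site replicate 1 4 were called, and without miR-194 replicate 1 668. At MOI60 and in the pooled fit 0 genes passed (limma; 883 and 336 at unadjusted p under 0.05). With miR-192 sites at MOI120, Msn, a membrane-cytoskeleton linker and a known target, rose by 0.35, Rprd1b rose by 0.41 and the complex I subunit Ndufb2 fell by 0.72 (limma adjusted p = 0.0348 each). Without a miR-192 site, Msn stood at 0.14 in both the pooled miR-194 and the pooled 7mer fit, not called. With let-7 at MOI63 it stood at -0.056. The miR-192 list stood at 0.035 (adjusted p = 0.336). Site and no-site libraries ran in different lanes here, so lane and site cannot be told apart. Leaving out either no-site library left 0 genes (limma), and leaving out miR-192 replicate 2 left 35. Across 19 comparisons with a list for their own miRNA, that list ranked first of 6 in 12, and the 95 shifts of other lists ran from -0.084 to 0.16.

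Total Aldoa did not follow the nominal dose across sets. It reached 33665 ± 132 FPKM (SD, n = 2) with no site at MOI11, or 5.85% of all FPKM, and 95118 ± 2522 at MOI63, or 17.65%. In the second MOI63 set it reached 32.05%, with no site at MOI120 19.7% (105212 FPKM), and in the MOI80 arm with the let-7 site 31.1%. Across arms it rose by 2.14 log2 from MOI11 to MOI63 (limma adjusted p = 1.24e-12) and by 0.45 from MOI60 to MOI120 (limma adjusted p = 0.0165). Reads of the endogenous and the viral transcript were not separated. With the 8mer at MOI11, total Aldoa fell by 0.54 log2 (limma adjusted p = 0.0196), to 23280 ± 188 FPKM. Leaving out any 1 of the 4 libraries ended this call at an unchanged size, from -0.54 to -0.55. At MOI20 and MOI63 the 8mer differences were -0.16 and -0.007, and for the 7mer they were -0.31 at MOI11 and 0.24 at MOI63, none past the threshold (limma adjusted p = 0.997, 0.977, 0.0976 and 0.315). Pooled over doses the 8mer difference was -0.23 (limma adjusted p = 0.485). The authors' deposited group values for Aldoa in hepatocytes are higher and give other differences. With the 8mer they stand at -0.65 at MOI11, -0.19 at MOI20 and -0.42 at MOI63 (177000 to 132355 FPKM), and with the 7mer at -0.40 at MOI11 and 0.035 at MOI63. At MOI80 they give -0.31, against -0.255 here. The FPKM interval of Aldoa implied 2349 to 2654 fragments in every hepatocyte library, at levels from 23148 to 177946 FPKM, so it does not follow its level. The cause of these disagreements was not tested, and how the effect of the 8mer on Aldoa depends on dose stays open.

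Far more genes differed between virus doses than with any site. The fit from MOI11 to MOI63 compares 8 libraries with 8, while site comparisons at a single dose compare 2 with 2. Differences in the preparation of the cells between doses are not excluded. From MOI11 to MOI63, over 4 arms, 3414 genes were higher and 3480 lower of 10432. The insulin-like growth factor binding protein gene Igfbp1 fell by 3.13 ± 0.072 (SE), from 206 ± 23.1 to 19.5 ± 0.0515 FPKM in the no-site groups (SD, n = 2; limma adjusted p = 1.59e-14). Ctgf and Cyr61, matrix genes of the YAP response, fell by 2.29 and 2.28, the kinase gene Sgk1 fell by 2.28, and Efr3b and Sema6a rose by 2.52 and 2.50. Of 23 interferon response genes 20 fell, among them Ifit1 at -1.59 and Ifit2 at -1.29. The list stood at -0.76 (adjusted p = 0.690 with an estimated correlation). Of 17 cholesterol synthesis genes 15 fell and 1 rose, among them Fdps (-0.96), with a list value of -0.56 (adjusted p = 0.0758 with an estimated correlation). Of 18 glycolysis genes 11 fell and 1 rose, with the glucose transporter Slc2a2 at -1.26 and Pklr at -0.96 (list -0.30, adjusted p = 0.0127, and adjusted p = 0.690 with an estimated correlation). Of 16 p53 response genes 12 rose and 2 fell, with Eda2r at 1.03, Ccng1 at 0.67, Plk2 at 0.66 and Btg2 at -1.24 (list 0.26, adjusted p = 0.0127, and adjusted p = 0.0758 with an estimated correlation). The stress genes Ddit3 and Atf4 rose by 1.93 and 1.05, but 6 of 14 members of their list fell and the list did not pass (0.33, adjusted p = 0.395). Among hepatocyte genes G6pc fell by 1.5 and Apob by 0.65, with 9 of 19 lower, 3 higher and the list at -0.15 (adjusted p = 0.395). The miR-194 list was higher by 0.27, with 9 of 13 higher and 2 lower (adjusted p = 0.0262, and adjusted p = 0.127 with an estimated correlation). Without scaling the median of all genes moved by -0.28, and 1355 genes were higher and 6734 lower, so these changes are relative to the median gene.

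From MOI60 to MOI120, 713 genes were higher and 625 lower of 10135. Of 11 cell cycle genes 6 fell, among them Rrm2 (-0.56) and Ccne2 (-0.55), and E2f7, a repressor of cell cycle genes, fell by 1.18 (list -0.29, adjusted p = 5.2e-05, and adjusted p = 0.349 with an estimated correlation). Of 17 cholesterol synthesis genes 9 fell, among them Hmgcs1 (-0.44) and Cyp51 (-0.42), with the list at -0.24 (adjusted p = 5.2e-05, and adjusted p = 0.349 with an estimated correlation). The chemokine gene Cxcl2 rose by 1.09 and Nfkbia, an inhibitor of NF-kB, by 0.41, and 5 of 11 NF-kB and cytokine genes rose in all (list 0.33, adjusted p = 0.00571, and adjusted p = 0.414 with an estimated correlation). Of 16 acute phase genes 6 rose and 1 fell, with Saa1 at 0.36 (list 0.15, adjusted p = 0.00351, and adjusted p = 0.414 with an estimated correlation). Atf3, Ddit3 and Socs3 rose by 0.71, 0.57 and 0.60, and the galectin gene Lgals1 fell by 1.15. Glycolysis genes stood at -0.22 with Pklr called (adjusted p = 0.00223, and adjusted p = 0.414 with an estimated correlation), and the miR-194 list at 0.26 with 5 of 13 higher (adjusted p = 0.00164, and adjusted p = 0.414 with an estimated correlation). The count fell to 468 without replicate 2 of the MOI60 no-site group, and to 542 without replicate 2 of the MOI120 no-site group. It was 890 without MOI60 no-site replicate 1, 681 without MOI60 miR-194 replicate 2 and 701 without MOI120 miR-194 replicate 1. Without scaling the median gene moved by -0.20, and 204 genes were higher and 3579 lower. Within each arm the doses ran in different lanes.

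**Figure D2:**
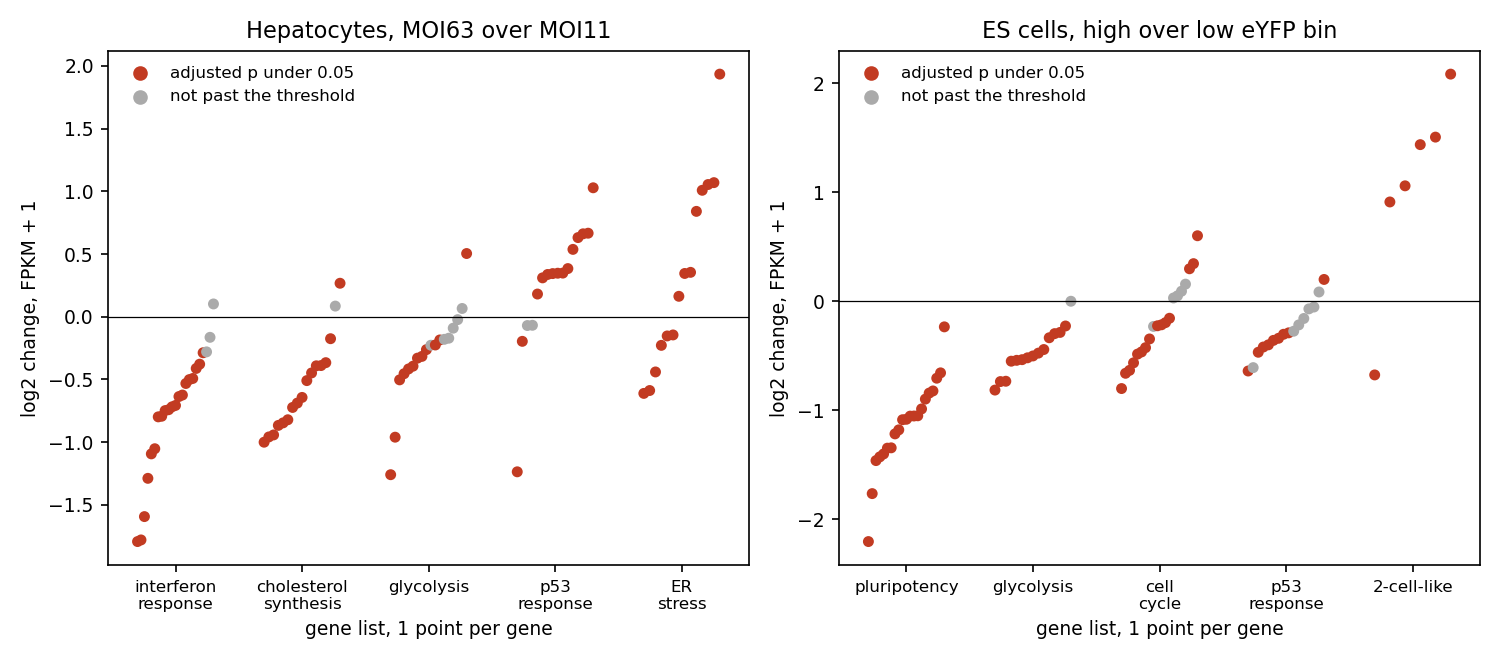
Log2 change of each gene (y axes, on FPKM + 1) in 5 gene lists (x axes, 1 point per gene, sorted within a list), with genes past an adjusted p of 0.05 in red. Of 23 interferon response genes 20 fell with virus dose, and of 21 pluripotency genes 21 fell in the high eYFP bin.

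In ES cells the first measurement was the reporter itself. The mCherry to eYFP ratio of transcript levels was 0.518 ± 0.00495 in the high bin, 0.562 ± 0.00636 in the intermediate and 0.668 ± 0.0509 in the low bin with no site (SD, n = 2). With 3 miR-293 sites it was 0.229, 0.194 and 0.255, or 38.7% of the no-site ratio. With 3 miR-92 sites it was 0.302, 0.279 and 0.346, or 53.1% of the no-site ratio. Both drops, of -1.37 and -0.91 log2, held in every bin, and miR-293 sites lowered the ratio more than miR-92 sites by a further -0.46 (exact permutation over every arrangement within bins, two-sided p = 0.00926 each, the smallest possible). mCherry fell by 1.55 ± 0.078 with miR-293 sites (limma adjusted p = 6.86e-07) and by 1.08 ± 0.082 with miR-92 sites (limma adjusted p = 9.14e-05). eYFP, on the same reporter without sites, stood at -0.18 and -0.17 (limma adjusted p = 0.661 and 0.952).

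Beyond mCherry few genes were called with the reporter's sites. mCherry was the 1 gene called in each pooled fit (limma; 923 of 12255 and 578 of 12230 genes at unadjusted p under 0.05), and it was called in every single bin. After quantile normalization it stood at -1.10 and -0.80 and was not called in the pooled fits (limma adjusted p = 0.587 and 0.926). In the single high bin that step gave mCherry a change of 0 with both constructs, since values of the same rank are set equal. In the intermediate and low bins mCherry stood at -1.54 and -1.64 with miR-293 sites after that step. With miR-92 sites the values there were -1.24 and -1.05, and all of these were called. With the replicate number as a block, mCherry kept its size but lost its miR-92 call in every bin (limma adjusted p = 0.124, 0.0651 and 0.253, high to low). With only the 2 groups compared, its miR-293 call was lost in the high and intermediate bins (limma adjusted p = 0.159 and 0.0518). Its miR-92 call was lost there in the high and low bins (limma adjusted p = 0.9997 and 0.828). With miR-293 sites mCherry was called in each bin whichever library was left out. With miR-92 sites in the high bin it stood at -1.005 to -1.065 and lost its call without any 1 of the 4 libraries. In the intermediate bin the call was lost without miR-92 replicate 1 (-1.19) or 2 (-1.20), and in the low bin without miR-92 replicate 1 (-1.13) or 2 (-0.91) or no-site replicate 2 (-0.87). The other calls were in the high bin, where Gm21060 fell with both constructs and 4930529M08Rik rose with miR-293 sites. Gm21060 was listed at 0 FPKM in all site libraries of that bin, against 63.2 ± 58.2 FPKM with no site, and 4930529M08Rik stood at 17.6 ± 16.3 FPKM against 0.351 ± 0.256 (SD, n = 2). Both were chosen after their values were seen. The miR-92 list, with Bcl2l11 and Klf2 among its members, was 0.037 higher over the bins (exact permutation p = 0.315), with values of 0.050, 0.016 and 0.045 in the high, intermediate and low bins. Leaving out 1 library turned the sign in each bin. No list holds targets of miR-293 itself. Pluripotency genes were lower with miR-293 sites, at -0.090, and with miR-92 sites, at -0.077 (adjusted p = 4.47e-04 and 0.0127, and adjusted p = 0.216 and 0.354 with an estimated correlation), with 0 of 21 genes called in either. By bin the score differences were -0.15, -0.12 and 0.002 with miR-293 sites in the high, intermediate and low bins, and -0.13, -0.097 and -0.001 with miR-92 sites, so the low bin shows none. Whether the bins differ was not tested. Cell cycle genes stood at -0.071 with miR-293 sites (adjusted p = 0.00781, and adjusted p = 0.200 with an estimated correlation). Both constructs share the no-site libraries. Replicate 2 of the low no-site group stood apart by 1.60 times the median, and without replicate 1 of that group 86 and 71 genes were called in the low bin for miR-293 and miR-92.

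**Figure D3:**
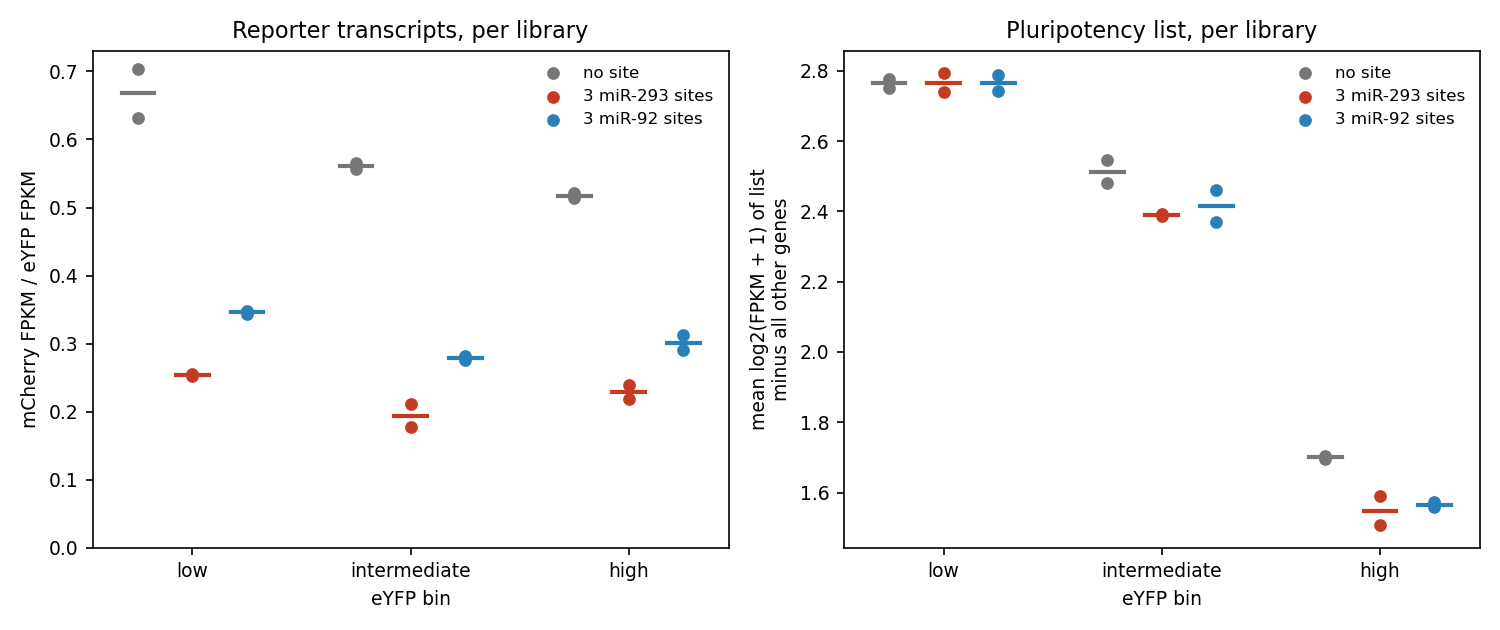
Left, mCherry over eYFP (ratio of FPKM, y axis) by eYFP bin (x axis), and right, mean log2(FPKM + 1) of 21 pluripotency genes minus that of all other genes (y axis, log2 units, not from 0), 1 point per library and a bar for the mean of n = 2. The highest pluripotency score in the high bin was 1.70 and the lowest in the low bin was 2.74.

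The last comparison set the high against the low eYFP bin over the 3 constructs. All 21 pluripotency genes measured fell in the high bin, with a list value of -1.16 (adjusted p = 1.29e-17, and adjusted p = 0.0145 with an estimated correlation). Nanog, a core factor of pluripotency (chromosome 6, 122707489 to 122714633, mm10), fell by 2.2 ± 0.081 (SE), from 151 ± 11.6 to 39.4 ± 4.42 FPKM with no site (SD, n = 2; limma adjusted p = 3.15e-09). Klf2 fell by 1.76, Esrrb by 1.43, Klf4 by 1.35, Fgf4 by 1.34 and Zfp42 by 1.08. Of 15 glycolysis genes 14 fell, among them Ldha (-0.81), Hk2 (-0.73) and the glucose transporter Slc2a1 (-0.73), with the list at -0.49 (adjusted p = 2.71e-07, and adjusted p = 0.0375 with an estimated correlation). Of 20 cell cycle genes 12 fell and 3 rose, with Ccne1 at -0.80, Mcm6 at -0.66 and Rrm2 at -0.63 (list -0.22, adjusted p = 0.0121, and adjusted p = 0.0549 with an estimated correlation). Of 16 p53 response genes 8 fell and 1 rose, with Bbc3 at -0.64 and Zmat3 at -0.47 (list -0.30, adjusted p = 0.0118, and adjusted p = 0.0549 with an estimated correlation).

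Other groups split or failed as lists. Markers of primed and early differentiating cells moved both ways, with Nes (0.91) and Krt8 (0.88) higher and Dnmt3b (-0.82) and Otx2 (-1.09) lower, and their list stood at 0.037 (adjusted p = 0.884). The 2-cell-like genes Zscan4d and Zscan4c rose by 2.09 and 1.44, 5 of 6 members rose and Eif1a fell by 0.67, but the list did not pass (1.03, adjusted p = 0.0585). The largest single changes were Pcp4 at 5.17, the imprinted gene Dlk1 at 3.99, Pck1, of gluconeogenesis, at 3.34, and Tdh, the threonine dehydrogenase of mouse ES cells, at -2.45. Ccnd1 fell by 1.91. eYFP and mCherry transcripts rose by 2.23 and 2.00. In all 2710 genes were higher and 2751 lower of 12303. Without scaling the median gene moved by 0.12, and 3759 genes were higher and 1879 lower. The gate selects on reporter level, so the bins differ in eYFP by construction.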

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

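The tests on libraries that stand apart, on genes specific to the MOI63 libraries, on library depth and on exit from the naive state were chosen only after the results were seen. The differences between groups came from tests of the difference itself, planned before the data were examined. The miR-122 list shift grew from MOI11 to MOI63 by 0.189 with the 8mer (28 of 33 members, median 0.139; adjusted p = 5.5e-10), by 0.126 with the 7mer (20 of 33, median 0.0203; adjusted p = 0.0141) and by 0.0975 with the 6mer (23 of 33, median 0.149; adjusted p = 0.0141). The 7mer median lies far below its mean shift, so the growth is not shared evenly over the list. The 7mer and 6mer values fell to 0.107 and 0.0786 without MOI11 no-site replicate 1 (adjusted p = 0.0639 each), and the 6mer one stood at 0.0997 without MOI63 6mer replicate 2 (adjusted p = 0.0642).

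The list was higher with the 8mer than with the 6mer by 0.0684 at MOI11 (26 of 33 members above 0), by 0.0745 at MOI20 (24 of 33) and by 0.160 at MOI63 (24 of 33), with adjusted p = 0.0130, 0.01002 and 4.51e-06. It was higher with the 8mer than with the 7mer by 0.0878 at MOI63 (20 of 33 members above 0), while 0.0245 at MOI11 (13 of 33; median -0.0030) and 0.0391 at MOI20 (22 of 33) did not pass (adjusted p = 0.435 and 0.0660). Pooled over doses these differences were 0.102 and 0.0516 (exact permutation p = 0.00926 each, the smallest possible), but at MOI11 and MOI20 lane and site type cannot be told apart. At MOI11 the 8mer to 6mer call was lost without 8mer replicate 2 (0.0595, adjusted p = 0.0876), and at MOI20 without 6mer replicate 2 (0.0641, adjusted p = 0.0685). At MOI63 the 8mer to 7mer call was lost without 8mer replicate 1 (0.0850) and without 7mer replicate 1 (0.0642). The reporter ratio was lower with miR-293 than with miR-92 sites by -0.457 log2, in each of the 3 bins.

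For the genes called at MOI63 with the 8mer, the count of 255 fell to 30 without the 8mer library that stands apart and rose to 1028 without the other one. It was 43 and 99 without each no-site library. With the 6mer it fell from 198 to 5 without the library that stands apart, rose to 487 without the other, and was 6 without no-site replicate 2. Both counts thus depend on single libraries, controls among them, and not on the library that stands apart alone. The 124 genes called higher with the 8mer outside the miR-122 list were also higher in the separate MOI80 libraries, by 0.176, with 108 of them in the same direction (p = 2.52e-05 with an estimated correlation), which argues against a change specific to the MOI63 libraries. The 122 genes called lower stood at -0.0467 there (87 in the same direction; p = 0.587 with an estimated correlation), and for them the explanation stays open. For the 6mer, 93 genes called higher stood at 0.0820 (65 in the same direction; p = 0.0718 with an estimated correlation). The 101 called lower stood at -0.0755 (75 in the same direction; p = 0.263 with an estimated correlation). For both the explanation stays open too, since the MOI80 libraries carry an 8mer and a let-7 site and no 6mer. An effect of the site on genes beyond its list stays a hypothesis for the higher 8mer genes.

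For the pluripotency genes lower in the high eYFP bin, library depth was set against a change of cell state. The list stood at -1.163 when the 6 high libraries were set against the 3 low libraries of similar implied depth, and at -1.16 over all libraries. The high libraries had 11.25 to 25.5 M implied fragments and those low libraries 15.04 to 29.8 M. This argues against depth only so far as the interval widths follow it, which was not tested. If cells leaving the naive state gathered in the high bin, markers of primed and early differentiating cells could be higher there. Their list stood at 0.0374 with members going both ways, which decides nothing. The state of the cells and their level of reporter, on which they were sorted, cannot be told apart here.

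For the virus dose, sequencing lane was weighed. Of 5709 genes called from 5 MOI63 and 4 MOI11 libraries outside lane 3, 5346 (93.64%) moved in the same direction between 2 MOI63 and 6 MOI20 libraries within lane 3, which argues against lane as the cause. Preparation of the cells stays open, since preparation dates are not given in the sources used here, and no other biological explanation was tested.

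Other splits of the same libraries within dose or bin were counted against the real ones. For virus dose from MOI11 to MOI63, 1 of 100 splits, the real one, reached 6894 genes, and the highest other gave 1. For the eYFP bins 1 of 100, the real one, reached 5461 and the highest other gave 1. Both shares argue against a chance division of these libraries. They cannot exclude differences between cultures or preparations that go with dose or bin, since every other split mixes the doses or bins. From MOI60 to MOI120 the real split gave 1338 genes and the highest other 0, but 18 splits are too few for a share under 0.05. With 1 gene called for miR-293 and 1 for miR-92, 7 and 10 of 100 splits gave as many, with 1 and 3 as the highest of the others, so the counts alone do not exclude chance. The gene is mCherry in both, whose libraries with and without sites were separated in every bin. With 0 genes called (limma), all 100 splits gave as many for the 8mer, 7mer, 6mer and let-7, as any split must, so this decides nothing. The highest others were 68, 27, 1 and 2. The 68 came from swapping the groups at MOI20 alone, and its cause was not tested. For miR-194, with 0 genes called (limma), all 18 splits gave as many, as they must, and the highest other gave 1. The 18 splits are also too few for a share under 0.05.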

How the results depend on the processing

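The settings without the libraries that stand apart, and leaving out libraries for the reporter ratio, were chosen after the data were seen. Where a library is left out, the lone sample of its group is assumed to vary like the other groups. Of 480 results with a library left out 401 kept their direction and side of the threshold, or a count within 1.5 times, and of 451 under the other alternatives 342 did. Of the values of named genes, 975 of 1087 and 542 of 649 did, and where no cause is given below the cause was not tested.

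With a pseudocount of 0.1, the count was 0 for let-7 at MOI63 (1 before), 7 for miR-192 (3), 1 for miR-293 (3) and 1 for miR-92 (2) in the high bin, 3 for miR-293 in the low bin (1) and 1 for the pooled 7mer (0). With no filter on low values, it was 3 and 2 for the 7mer and 6mer at MOI11, 1, 1, 3 and 1 for the 8mer, 7mer, 6mer and let-7 at MOI20, 23 for let-7 at MOI63, 21 for miR-194 at MOI60 and 147 at MOI120, 72 for miR-192, 77 at MOI80, 4 for miR-92 in the high bin and 3 for miR-293 in the intermediate bin. More genes are tested there.

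With values as deposited and no scaling, 814, 11 and 56 genes were called with the 8mer, 7mer and 6mer at MOI63 (255, 19 and 198 before), 4 with let-7 at MOI63, 1 with miR-192, 156 at MOI80 (48) and 3783 from MOI60 to MOI120 (1338). Aldoa with the 8mer at MOI63 turned to 0.0866 (-0.0068 before). With quantile normalization the counts were 0 for the 8mer and 3 for the 7mer at MOI11, 392, 46 and 3 for the 8mer, 7mer and let-7 at MOI63, 40 for miR-194 and 1 for miR-192 at MOI120, 0 for both constructs in the high bin, 2 for both in the intermediate bin, 1 for the pooled 7mer and 0 for both pooled constructs. The 8mer shift at MOI11 was 0.0450 (adjusted p = 0.0644), and the miR-92 difference between bins turned to -0.00178. eYFP, in both constructs and between bins, Aldoa between MOI60 and MOI120, and mCherry in the high bin in both constructs came to 0, since values of the same rank are set equal in every library.

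The replicate numbers did not pair the groups (r from -0.47 to 0.37 over 41 pairs of groups). With the number as a block, 129 genes were called with the 6mer and 0 with let-7 at MOI63, 3 with miR-194 at MOI60, 5 with miR-192, 1 with miR-293 and 0 with miR-92 in the high bin, 0 with miR-92 in the intermediate and low bins, 2 with miR-293 in the low bin and 640 from MOI60 to MOI120. The 8mer shift at MOI11 was 0.0481 (camera, limma adjusted p = 0.0572). The pooled shifts of 0.127, 0.0754 and 0.0970 for the 8mer, 7mer and let-7 had adjusted p = 0.0625 each (exact permutation within pairs, adjusted over 6 tests). That test has fewer arrangements.

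With a filter at a mean of 10 FPKM, the 7mer shift at MOI11 was 0.0907 (adjusted p = 0.0478, now past the threshold), let-7 stood at 0.0792 at MOI11 and 0.0808 at MOI20 (adjusted p = 0.0559 each), the 7mer at MOI20 at 0.0324, its growth with dose at 0.0390, and the 8mer over the 6mer at MOI20 at 0.0376. miR-92 turned to -0.0277 in the intermediate bin and -0.0688 between bins, and the 8mer over the 7mer at MOI11 to -0.0240. With a background matched on mean expression, the 8mer shift at MOI11 was 0.0487 (adjusted p = 0.0928), miR-92 between bins -0.0160, and the 8mer over the 7mer at MOI20 0.0406 (adjusted p = 0.0460, now past the threshold).

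With only the 2 groups compared in the fit, the counts were 984, 4 and 1 for the 7mer, 6mer and let-7 at MOI11, 1 for the 8mer at MOI20, 0 for the 8mer, 7mer, 6mer and let-7 at MOI63 and 0 at MOI80 (limma), 1 for miR-194 and 1 for miR-192 at MOI120, 0 for miR-293 and 1 for miR-92 in the high bin, 0 and 6 in the intermediate bin and 2 for miR-293 in the low bin. Fewer libraries estimate the spread there. Without the libraries that stand apart they were 45 and 5 for the 8mer and 6mer at MOI63, 3 for miR-194 at MOI120 and 2 for miR-293 in the low bin, and the miR-92 shift in the low bin turned to -0.0337.

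With an estimated correlation between genes, the lists past the threshold fell to 0 for the pooled 8mer, 7mer, 6mer, miR-293 and miR-92 (1, 6, 3, 4 and 4 before) and for both virus dose comparisons (5 and 6), to 1 for pooled let-7 (5), to 1 each for the 8mer and let-7 at MOI63 (2 each) and to 2 for the eYFP bins (4). Without the most abundant miRNA, RPM rose to 107317 for let-7, 27585 for miR-192, 42576 for miR-194 and 10409 for miR-92 in hepatocytes, and in the ES libraries to 74876 and 80272 for miR-293 and to 35853 and 32222 for miR-92, since the total is smaller.

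Leaving out libraries gave these ranges of the count of genes called, with the libraries that moved it by more than 1.5 times. At MOI11 it was 0 to 4 for the 8mer (4 without 8mer replicate 2, 0 without each other library) and 0 to 1 for the 7mer (0 without 7mer replicate 2). At MOI63 it was 30 to 1028 for the 8mer, 5 to 21 for the 7mer, 5 to 487 for the 6mer and 0 to 3 for let-7 (2 and 3 without no-site replicates 1 and 2, 0 without let-7 replicate 1). It was 0 to 10 for miR-194 at MOI60 (3 and 10 without miR-194 replicates 1 and 2) and 4 to 668 at MOI120, 0 to 35 for miR-192 and 21 to 64 at MOI80. From MOI60 to MOI120 it was 468 to 1229, from MOI11 to MOI63 6589 to 6954 and between eYFP bins 4757 to 5526. In ES cells it was 1 to 4 for miR-293 (1 without no-site replicate 1 or miR-293 replicate 2) and 0 to 1 for miR-92 in the high bin (1 without no-site replicate 2, 0 without no-site replicate 1 or either miR-92 library). It was 1 to 4 and 0 to 4 in the intermediate bin (4 each without no-site replicate 2, 2 and 0 without miR-92 replicates 1 and 2). It was 2 to 86 and 0 to 71 in the low bin (86 and 71 without no-site replicate 1, 2 for miR-293 without no-site replicate 2 or miR-293 replicate 2, 4 without miR-293 replicate 1, 0 for miR-92 without miR-92 replicate 2). Pooled it was 0 to 1 for the 7mer (1 without MOI11 7mer replicate 2 or MOI20 7mer replicate 1) and 1 to 3 for miR-293 (3 without low miR-293 replicate 1).

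Shifts ranged as follows. The 8mer at MOI11 gave 0.0292 to 0.0668 (lost without no-site replicate 2, adjusted p = 0.274, and at 0.0392 without 8mer replicate 2, adjusted p = 0.279). let-7 gave 0.0576 to 0.0821 at MOI11 (lost without let-7 replicate 1, adjusted p = 0.124) and 0.0677 to 0.0940 at MOI20 (lost at 0.0762 without let-7 replicate 2, adjusted p = 0.0527). The 7mer at MOI20 gave 0.0392 to 0.0639 (lost at 0.0392 without no-site replicate 2, and at 0.0521 and 0.0512 without 7mer replicates 1 and 2). The 6mer at MOI63 gave 0.0751 to 0.0793 (lost at 0.0774 without no-site replicate 1, adjusted p = 0.0543, and at 0.0793 without 6mer replicate 2, adjusted p = 0.0876). The 8mer over the 6mer gave 0.0595 to 0.0771 at MOI11 and 0.0641 to 0.0849 at MOI20, and the 8mer over the 7mer gave 0.0642 to 0.111 at MOI63. Growth with dose gave 0.102 to 0.149 for the 7mer, 0.0786 to 0.116 for the 6mer and 0.0565 to 0.0818 for let-7 (past the threshold at 0.0815 without MOI11 let-7 replicate 1, adjusted p = 0.0346). miR-194 gave -0.0101 to 0.0918 at MOI60 (turned without miR-194 replicate 1) and -0.00937 to 0.0925 between MOI60 and MOI120 (turned without MOI60 miR-194 replicate 2). miR-92 gave -0.00818 to 0.109 in the high bin (turned without miR-92 replicate 1), -0.0162 to 0.0479 in the intermediate bin (turned without no-site replicate 2, and at -0.00537 without miR-92 replicate 1) and -0.0337 to 0.124 in the low bin (turned without no-site replicate 2). Between bins it gave -0.0734 to 0.0842 (turned at -0.0734 without low no-site replicate 1, -0.0353 and -0.0532 without high no-site and miR-92 replicate 1, and -0.00223 without low miR-92 replicate 2). The reporter ratios kept their sign and call throughout.

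Targets with an 8mer only, a background matched on 3' UTR length and count-based tools were not run, since they need genome sequence or counts of fragments. What depth limits was not tested, since no library was thinned. In simulated libraries with the spread of the data, 9% of genes changed by 0.25 log2 were recovered at MOI63 with the 8mer and 0% in a single ES bin. The noise there was independent between genes, so recovery in the data may be lower.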

Other observations

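Cell type markers were mostly too few to test. Lists of Kupffer and stellate cell markers had fewer than 3 members measured and were not tested. In ES cells, between the high and low eYFP bins, 3 markers each of liver endothelium, cholangiocytes and lymphocytes stood at -0.36, -0.33 and 0.27 (adjusted p = 0.645, 0.362 and 0.547). Spp1, the osteopontin gene, fell by 0.90 there.

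The ER stress and amino acid list stood at 0.057 with miR-293 sites and 0.069 with miR-92 sites, and the miRNA machinery list at -0.094 with miR-92 sites, all in ES cells (adjusted p = 0.574, 0.354 and 0.386 with an estimated correlation). In hepatocytes the iron hormone gene Hamp fell by 0.93 from MOI11 to MOI63, while the acute phase list stood at -0.082 with 4 genes higher and 6 lower.

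Both tests here were planned before their results were seen. The first hypothesis was that members of the miR-122 list rise by similar amounts in separate experiments, the 8mer at MOI63 and both sites at MOI80, which share no library. Over 33 genes Pearson's r was 0.714 (permutation p = 1e-05, the smallest that 100000 permutations can give), and Spearman's rho was 0.777. Members that rose more in 1 experiment thus tended to rise more in the other, a reading limited to members of 1 list. Genes outside the list were not correlated in this way, so whether these sizes are particular to the site stays open.

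The second hypothesis was that the intermediate eYFP bin lies between the others in its pluripotency score. The score changed by -0.326 from low to intermediate and by -0.834 from intermediate to high, each in all 3 constructs (exact permutation p = 0.00926 each, the smallest possible). The decline could thus go with reporter level rather than with the high gate alone.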
